A study of Trichoderma asperellum with 9 samples.

How the data were processed

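RNA-seq was performed on 9 libraries of total RNA from strain Ts93 of Trichoderma asperellum, a filamentous soil fungus of a genus used for biological control of plant pathogens. Per the labels, the strain is wild type and was grown as a control, with 0.5 mM BCS or with 1 mM copper ions, with 3 libraries in each of the 3 groups. The labels do not spell out BCS. The abbreviation is widely used for bathocuproine disulfonate, a chelator of copper, and that reading is background here, not a label. RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

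The authors deposited 1 table of FPKM values (fragments per kilobase of gene model, scaled to library size), with 1 column per library and no pooling of replicates. Per the submitters' processing notes, Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq 1.18.0 were used, with no stated role. The notes also list mm8, a mouse build, which cannot be the genome of a fungus, and the genome and annotation behind the gene models are not given in the sources used here. The table held 9396 gene models, of which 7043 carried a strain-specific number with the prefix 93-3_5.6A and 2353 had an identifier of the type of Novel00378 (called supplementary models here, as their origin is not given in the sources used here). None of the identifiers (0 of 9396) matched a gene identifier, locus tag or accession in the reference table of 12041 genes of T. asperellum FT101, and the deposited table pairs them with no name or function. Gene names, functions and genomic coordinates are therefore not reported, and the gene lists and protein motifs chosen before the data were examined could not be filled. At most 2 rising and 2 falling identifiers were named per comparison, by a rule chosen before the data were examined. The rule took the largest log2 fold changes among models that passed the test, whose 3 libraries in 1 group all lay above the 3 in the other, and whose higher group had a mean FPKM of at least 5. A few further identifiers, singled out after their values were seen, are marked as such.

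The depth was recovered from the deposited FPKM values, because each value is a whole number of reads times the worth of 1 read for that model and library. The read total that fitted each library lay within 4e-05 of a whole number, and the reads recovered over all models summed to between 99.95% and 99.98% of that total. The totals ranged from 12335534 to 17142918 reads assigned to the listed models. All values above 0 (100.0%) came out whole within a tolerance of 0.01 reads once a model length was chosen, a condition that the choice of length makes easy to meet for models with few reads. Fitted lengths of the numbered models were divisible by 3 in 99.9% of cases, so these are coding lengths, with a median of 1149 bases. Lengths of the supplementary models were divisible by 3 in 33.9% of cases and had a median of 1978 bases. On simulated data, all 9 library totals were recovered, and every read number was exact for 99.88% of the 2600 simulated models with at least 50 reads. Chi-square values per degree of freedom between libraries of the same group ranged from 26.9 to 256, where counting noise alone gives about 1, so no library was the same library sequenced again; separate preparations of the same RNA are not excluded.

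FPKM values are not counts, so the main test was limma (version 3.58.1, R 4.3.3) with a mean-variance trend on log2(FPKM + 1). It was fitted to all 9 libraries with 1 mean per group and no block, and all fold changes are on that scale, which understates changes of weakly expressed models. Models with an FPKM of at least 1 in at least 3 of the 9 libraries were tested (7857 models). P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, and a model was called changed at an adjusted p under 0.05. The comparisons were copper against control, BCS against control and copper against BCS. On simulated data with 200 changed models, 4-fold changes were recovered for 95.0% of models in copper against control, 87.0% in BCS against control and 92.0% in copper against BCS (7634, 7631 and 7640 models tested). For 2-fold changes the same values were 32.0%, 48.0% and 31.0%, and false calls made up 8.6%, 4.9% and 4.7% of all calls. The simulation gave every comparison the same control means and the same spread per model, and left out differences in spread between groups. Differences between the comparisons in these values therefore reflect mainly the random draw. The 200 changed models were also fewer than the 750, 1342 and 2782 models called in the data. With fewer changed models the adjustment of p-values is stricter, so these values may understate the recovery in the data. The shares of called models among numbered and supplementary models were compared with Fisher's exact test, two-sided, over 6 tests. For the 2 comparisons that share the control libraries, 100 simulations without any effect gave the values that shared controls produce under independent noise. All 9 libraries, controls included, were drawn independently for each model, with the same spread in every group.

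Alternatives were other pseudocounts (0.1 and 5), no filter or a minimum FPKM of 5, 3 other scalings (TPM scale, median of ratios and quantile normalization), the replicate number as a block, a fit to the 2 groups compared alone, limma without trend, robust limma, library weights, and leaving out each library in turn. Voom on the recovered reads (limma) and a rescaling without the 10 most abundant models were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.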

Results

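The transcriptome of T. asperellum Ts93 was profiled under 3 conditions, which differed in copper supply or in exposure to BCS, to find the gene models that respond to copper stress. The control libraries held 13198011, 17142918 and 16747499 reads assigned to gene models, the BCS libraries 12338460, 14851276 and 13464887, and the copper libraries 12335534, 12576375 and 12836226. Between 7371 and 7640 of the 9396 models reached an FPKM of at least 1 in a library, and 408 models were at 0 in all 9. The most abundant model, 93-3_5.6A0895 (coding length 291 bases, singled out after its values were seen), had 127350 ± 23605 FPKM in the control, 60316 ± 32134 with BCS and 65039 ± 9039 with copper (mean ± SD, n = 3 each). Neither difference from the control passed the test (limma adjusted p = 0.17 for BCS and 0.33 for copper).

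The libraries separated by group on the first principal component, but control and copper did not separate by every measure. The first principal component held 60.5% of the variance and placed the BCS libraries between -69.6 and -41.7, the control libraries between 13.3 and 14.1, and the copper libraries between 40 and 45.1. The second component held 16% and spread the control libraries from -41.0 to -10.5. Across models, the log2 values of copper libraries correlated with each other at r = 0.986 to 0.992, those of control libraries at 0.963 to 0.973 and those of BCS libraries at 0.964 to 0.980. Correlations between groups were highest for control and copper (0.940 to 0.962), lower for BCS and control (0.881 to 0.933) and lowest for BCS and copper (0.855 to 0.899). Models are not independent replicates, so these correlations describe the libraries and carry no test. By chi-square per degree of freedom, control replicate 1 lay nearer to the copper libraries (162 to 197) than to the other controls (209 and 256). Control replicate 2 lay nearer to copper replicate 1 (192) than to the other controls (209 and 195). Every other library lay nearer to its own group than to any library of another group. The median standard deviation of a model within a group was 0.18 log2 units with copper, 0.25 in the control and 0.32 with BCS.

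**Figure D1:**
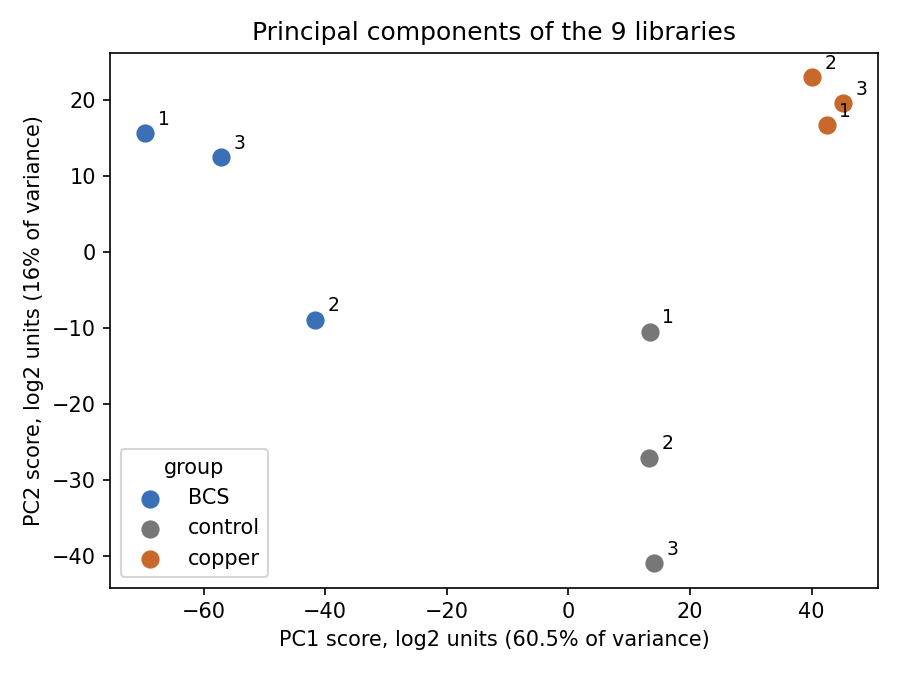
Scores of the 9 libraries on the first (x axis) and second (y axis) principal components of log2(FPKM + 1), in log2 units, with 1 point per library, coloured by group and numbered by replicate. The BCS libraries lie between -69.6 and -41.7 on the first component, the control libraries near 13 to 14 and the copper libraries between 40 and 45.1.

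Copper ions at 1 mM, compared with the control, addressed the response to copper excess. Of 7857 tested models, 523 were higher and 227 lower with copper. The changes were moderate in size: 321 models rose and 178 fell at least 2-fold, 66 rose and 56 fell at least 4-fold, and 4 rose and 2 fell at least 16-fold. Under the naming rule, the largest rise on the log2(FPKM + 1) scale was that of 93-3_5.6A0825 (coding length 957 bases). It rose from 1.70 ± 0.101 FPKM in the control to 86.0 ± 7.03 with copper (mean ± SD, n = 3), a log2 fold change of 5.01 ± 0.31 (SE, limma adjusted p = 1.5e-05). It stood at 1.66 ± 1.26 FPKM with BCS. Model 93-3_5.6A6785 rose from 1.14 ± 0.635 to 63.6 ± 16.7 FPKM, a log2 fold change of 4.94 ± 0.28 (limma adjusted p = 9.3e-06). By the ratio of mean FPKM it rose more than 93-3_5.6A0825, 55.76-fold against 50.59-fold. The largest fall on the log2(FPKM + 1) scale, under the same rule, was that of 93-3_5.6A4430. It fell from 574.5 ± 468.6 FPKM in the control to 23.1 ± 12.4 with copper, a log2 fold change of -4.41 ± 0.56 (limma adjusted p = 1.0e-03). Novel00378 fell from 64.7 ± 53.4 to 1.88 ± 0.444 FPKM, a log2 fold change of -4.21 ± 0.48 (limma adjusted p = 5.7e-04). By the ratio of mean FPKM it fell more than 93-3_5.6A4430, 34.45-fold against 24.92-fold. Of the 4 models, none passed the test in BCS against control, where Novel00378 came closest with a log2 fold change of 1.43 ± 0.48 (limma adjusted p = 0.064). Only 4 models lay below 1 FPKM in all control libraries and at or above 5 in all copper libraries, and 1 model showed the opposite.

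Of the 750 models changed by copper, 748 had no overlap between the 3 copper and the 3 control libraries. Such separation held for 36.6% of all tested models, against 10% by chance for a single model. Here and below, the 10% gives no test over models, since a shift of a whole library can separate many models at once. The calls come from the same values, so their separation is not separate support. The median log2 fold change of all tested models was 0.13, and the excess of rises depended on how libraries were scaled: 69.7% of called models rose in the FPKM as deposited, 49.1% after median-of-ratios scaling (375 higher, 388 lower), 51.6% after quantile normalization (422 higher, 396 lower) and 82.7% on the TPM scale (916 higher, 192 lower). The number of changed models depended on which libraries were used. It was 355, 301 and 289 without copper replicate 1, 2 and 3. Without control replicate 1, 2 and 3 it was 925, 507 and 463. It rose to 1135 without BCS replicate 2, which enters this comparison through the shared spread and the filter on low values (7780 models tested without it). Without BCS replicate 1 and 3 it was 766 and 696. Leaving out a copper or control library leaves that group with 2, so some fall is expected from the smaller group alone. Models changed at least 2-fold numbered 291 and 281 without copper replicate 2 and 3, against 499 with all libraries.

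BCS at 0.5 mM, compared with the control, addressed the opposite change in copper supply, if BCS is the chelator. It changed 1342 models, 569 higher and 773 lower. At least 2-fold changes numbered 394 rises and 540 falls, at least 4-fold changes 150 and 146, and at least 16-fold changes 38 and 22. Under the naming rule, the largest rise on the log2(FPKM + 1) scale was that of 93-3_5.6A6772 (coding length 681 bases). It rose from 1.5 ± 1.69 FPKM in the control to 597.2 ± 140.6 with BCS, a log2 fold change of 8.08 ± 0.38 (limma adjusted p = 1.5e-07). Model 93-3_5.6A0600 rose from 4.57 ± 1.88 to 1204 ± 125.3 FPKM, a log2 fold change of 7.81 ± 0.32 (limma adjusted p = 7.1e-08). Both were low with copper, at 1.78 ± 0.49 and 6.16 ± 2.64 FPKM, and neither differed from the control there (limma adjusted p = 0.63 and 0.57). The largest fall on the log2(FPKM + 1) scale, under the same rule, was that of 93-3_5.6A1435 (coding length 249 bases). It fell from 243.3 ± 71.8 FPKM to 2.04 ± 0.64, a log2 fold change of -6.31 ± 0.29 (limma adjusted p = 1.3e-07). This model fell with copper as well, to 53.6 ± 14.1 FPKM (log2 fold change -2.15 ± 0.29, limma adjusted p = 1.4e-03). Novel01429 fell from 1652 ± 440.4 to 22.4 ± 6.36 FPKM with BCS, a log2 fold change of -6.15 ± 0.28 (limma adjusted p = 1.3e-07), and stood at 2626 ± 541.8 FPKM with copper. In 15 models the FPKM was below 1 in all control libraries and at least 5 in all BCS libraries, and 8 models showed the opposite.

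Groups did not overlap for 1305 of these 1342 models, and for 27.5% of all tested models, against 10% by chance. The median log2 fold change of all tested models was -0.08, and rises made up 42.4% of the called models as deposited, 46.4% after median-of-ratios scaling and 48.0% on the TPM scale. The count was 755 without BCS replicate 1 and 858 without BCS replicate 3. Without BCS replicate 2, the BCS library nearest to the control on the first principal component, it was 2282, with 654 higher and 1628 lower, so that rises made up 28.7%. In fits to the 2 groups compared alone, BCS changed 909 models and copper 1026, the reverse of the order in the main fit. The main fit shares 1 estimate of spread per model, while the median SD was 0.32 log2 units with BCS, 0.25 in the control and 0.18 with copper. Which treatment changed more models therefore depended on whether the spread was shared over all groups.

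Copper against BCS compared the treatments directly. Its fold changes do not use the control libraries, but the copper and BCS libraries are those of the other comparisons. This comparison changed the most models, 2782 of 7857 (35.4%), with 1876 higher and 906 lower with copper. At least 2-fold differences numbered 1021 and 587, and at least 16-fold differences 55 and 62. Model 93-3_5.6A2564 (coding length 741 bases) had 616.7 ± 100.5 FPKM with copper, 190.4 ± 82.9 in the control and 3.36 ± 1.84 with BCS, a log2 fold change between treatments of 7.21 ± 0.36 (limma adjusted p = 2.2e-07). Model 93-3_5.6A0483 had 233.2 ± 171.9 FPKM with copper, 62.1 ± 49.0 in the control and 0.72 ± 0.259 with BCS (log2 fold change 6.87 ± 0.68, limma adjusted p = 3.3e-05). In the other direction, 93-3_5.6A2982 had 2.97 ± 2.23 FPKM with copper, 8.89 ± 5.99 in the control and 1033 ± 587.1 with BCS (log2 fold change -8.07 ± 0.56, limma adjusted p = 2.7e-06). Model 93-3_5.6A5268 (coding length 267 bases) had 23.6 ± 8.35 FPKM with copper, 265.7 ± 191.2 in the control and 6348 ± 4562 with BCS (log2 fold change -7.84 ± 0.60, limma adjusted p = 4.6e-06). In 33 models the FPKM was at least 5 in all copper libraries and below 1 in all BCS libraries, and 34 models showed the opposite.

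Of the 2782 models, 2722 had no overlap between the groups, and such separation held for 49.7% of all tested models, against 10% by chance. Of the same models, 1202 were called in neither comparison with the control. The median log2 fold change of all tested models was 0.24, and the share of rises was 67.4% as deposited, 49.8% after median-of-ratios scaling (1415 higher, 1429 lower) 51.3% after quantile normalization (1449 higher, 1374 lower) and 72.3% on the TPM scale (2177 higher, 834 lower). Without copper replicate 3 the count was 1814, and without BCS replicate 2 it was 3743, with 2856 higher and 887 lower.

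**Figure D2:**
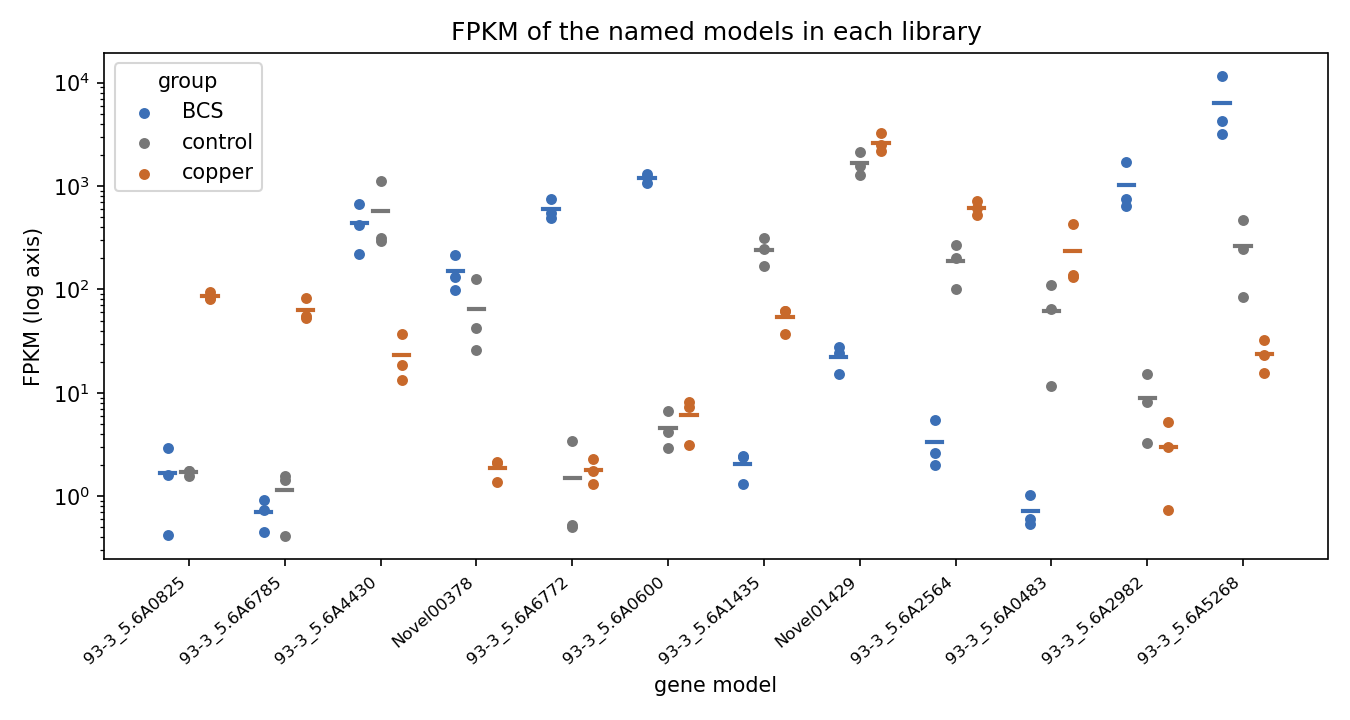
FPKM on a log axis (y axis) of the 12 models named in the 3 comparisons (x axis), with 1 point per library and a bar at the mean of each group of 3 libraries. Models 93-3_5.6A6772 and 93-3_5.6A0600 are high with BCS alone (597.2 and 1204 FPKM), and 93-3_5.6A0825 is high with copper alone (86.0 FPKM).

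Responses to the treatments overlapped in 212 models, which passed the test in both comparisons with the control. Of these, 122 moved in opposite directions and 90 in the same direction. Higher with copper and lower with BCS were 71 models, where independent lists of these sizes would share 51.5, and lower with copper and higher with BCS were 51 models, where independent lists would share 16.4. Model 93-3_5.6A2564 belonged to the former class, with a log2 fold change of 1.78 ± 0.36 in copper against control (limma adjusted p = 0.011) and -5.43 ± 0.36 in BCS against control (limma adjusted p = 3.4e-06). Model 93-3_5.6A5268 belonged to the latter class, with -3.19 ± 0.60 and 4.65 ± 0.60 (limma adjusted p = 7.7e-03 and 3.6e-04). Lower in both were 69 models, where independent lists would share 22.3, among them 93-3_5.6A1435. Higher in both were 21 models, where independent lists would share 37.9. Both comparisons use the same estimate of spread for each model, so models of low spread pass both more easily, in any direction. An excess over independent lists is therefore not by itself a sign of linked responses, in the opposite-direction classes included.

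Simulated groups without any effect, set against simulated controls that they shared, gave at most 1 call in either same-direction class over 100 simulations. They gave 0 in opposite directions. Such groups yield almost no calls, so this value does not measure how much the shared controls add where both treatments have effects. The Pearson correlation of the log2 fold changes over models was -0.06, against 0.50 in those simulations, and the covariance was -0.031 against 0.040, a difference of -0.071. The simulated correlation is fixed near 0.50 by the shared controls and equal group sizes, while real effects enter the observed value alone. These differences are therefore not a test of the overlap. With 3 control libraries the controls could not be split into parts of at least 2, so part of the same-direction overlap may come from the shared controls. The class sizes moved with scaling: after median-of-ratios scaling 105 models were lower in both, 63 were higher with copper and lower with BCS, 75 were lower with copper and higher with BCS, and 17 were higher in both. On the TPM scale the same classes held 58, 83, 44 and 41 models, and after quantile normalization 115, 66, 74 and 22, so that which opposite class was larger depended on the scaling. Without BCS replicate 2 the same-direction and opposite-direction classes held 186 and 227 models. Without copper replicate 2 they held 41 and 69, without copper replicate 1 they held 46 and 73, without copper replicate 3 they held 43 and 57, and without control replicate 3 they held 51 and 80. Without control replicate 2 they held 69 and 77, without BCS replicate 1 they held 87 and 93, and without BCS replicate 3 they held 69 and 93. Without control replicate 1 the order was reversed, with 143 models in the same direction and 92 in opposite directions.

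**Figure D3:**
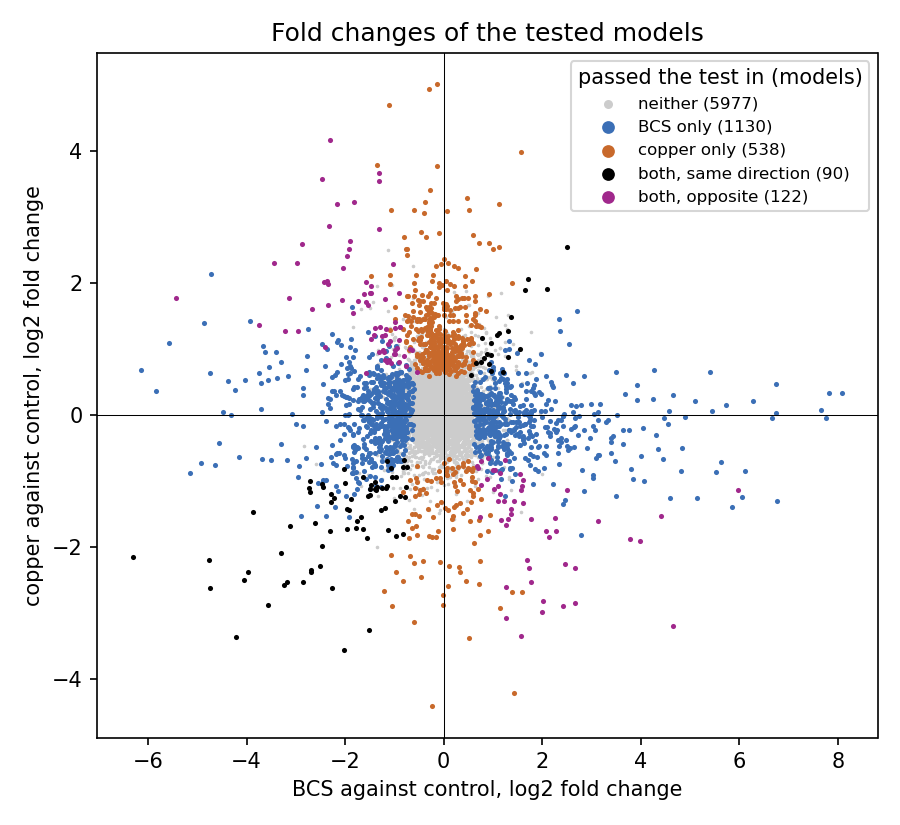
Log2 fold change of each tested model in BCS against control (x axis) and copper against control (y axis), with 1 point per model, coloured by the comparisons in which it passed the test. Of the models called in both, 122 lie in the quadrants of opposite sign and 90 in those of the same sign.

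The supplementary models, those with identifiers of the type of Novel00378, fell more often than numbered models. In BCS against control 13.1% of 1439 supplementary models fell, compared with 9.1% of 6418 numbered models (Fisher's exact test, adjusted p = 3.0e-05). In copper against control the shares that fell were 4.6% and 2.5% (Fisher's exact test, adjusted p = 1.1e-04), and in copper against BCS 15.9% and 10.5% were lower with copper (Fisher's exact test, adjusted p = 1.7e-07). These 3 differences kept their direction under the TPM scale, median-of-ratios scaling and quantile normalization. For rises the order varied, with 4.9% of supplementary and 7.0% of numbered models higher with copper than in the control (Fisher's exact test, adjusted p = 5.1e-03), compared with 7.4% and 12.6% on the TPM scale (Fisher's exact test, unadjusted p = 9.0e-09), 4.2% and 5.6% after quantile normalization (unadjusted p = 0.028) and 4.2% and 4.9% after median-of-ratios scaling (unadjusted p = 0.25). With BCS, 8.7% of supplementary and 6.9% of numbered models rose (Fisher's exact test, adjusted p = 0.025), which became 9.2% and 7.8% on the TPM scale (Fisher's exact test, unadjusted p = 0.076), 9.7% and 8.7% after quantile normalization (unadjusted p = 0.20) and 10.1% and 8.9% after median-of-ratios scaling (unadjusted p = 0.16). In copper against BCS, 22% of supplementary and 24.3% of numbered models were higher with copper, a difference that did not pass the test (Fisher's exact test, adjusted p = 0.070). Models are not independent replicates, so these tests describe the model sets. The sets differed in median length (1978 bases for supplementary and 1149 for numbered models), and no comparison matched for length or abundance was made. Of the 100 most abundant tested models, 4 rose and 4 fell with copper, and 5 rose and 13 fell with BCS, each against the control. In copper against BCS, 16 of these 100 models were higher and 24 lower with copper, while over all called models 67.4% were higher.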

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

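The choices below were fixed before the data were examined, except voom on the recovered reads and the rescaling without the 10 most abundant models. Of 114 counts and summary values under alternatives other than leaving out a library, 104 stayed within 1.5 times of the reported count or within 1 SD. Within that limit, fits to the 2 groups compared alone called 1026 models in copper against control and 909 in BCS against control. This reversed the order of 750 and 1342 in the main fit. Models changed at least 2-fold kept their order, at 542 and 795. The values outside the limit were as follows. A pseudocount of 5, which shrinks fold changes by construction, lowered the models changed at least 2-fold to 314, 618 and 1053 in copper against control, BCS against control and copper against BCS. Library weights raised the changed models to 1602, 2294 and 4584 in the same order, with 242 shared in the same direction and 278 in opposite directions. BCS replicate 2 received the lowest weight (0.21) and copper replicate 3 the highest (3.65). Quantile normalization raised the same-direction class to 137, and the cause was not tested. Over the 1000 models of highest variance the mean correlation within groups was 0.944, against 0.976 over all tested models. No call made in the main fits took the opposite sign as a call under any alternative, and voom called 724, 1355 and 2752 models. Leaving out 1 library at a time gave 289 to 1135 changed models in copper against control, 755 to 2282 in BCS against control and 1814 to 3743 in copper against BCS, and 281 to 658, 646 to 1248 and 1370 to 1979 changed at least 2-fold. The same-direction class ranged from 41 to 186 and the opposite-direction class from 57 to 227. Each such fit leaves 1 group with 2 libraries, which are assumed to vary like the other groups. All 276 values of the 12 named models kept their direction and passed the test, with a highest limma adjusted p of 0.0087. These 12 models were picked as the largest changes in the same libraries, so this says little about the other called models. No test of depth by thinning reads was run. At 3 libraries per group simulated 2-fold changes were mostly missed. That simulation changed 200 models, fewer than were called in the data, so it may understate the recovery there. Tests of gene lists were not run, because no identifier could be paired with a function.

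The replicate numbers 1 to 3 are shared by the groups but were not found to pair the libraries. Deviations from group means correlated between -0.28 and 0.21 for the 9 same-numbered pairs, only 1 of which exceeded 0.1, and 0 libraries correlated best with their own number in both other groups. Pairs of different numbers ranged from -0.31 (BCS replicate 2 with control replicate 1) to 0.33 (BCS replicate 2 with control replicate 3). A factor shared by libraries in another order is therefore not excluded. With the replicate number as a block, 556, 1152 and 2435 models were called in copper against control, BCS against control and copper against BCS.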

Other observations

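The tests of model length, of chance placement, of the longest runs and of the peak of the fold changes (which replaced the planned test on median-of-ratios scaling, since centring largely fixes its outcome), and the rescaling without the 10 most abundant models, were chosen after the data had been seen.

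Changed models sat next to each other in identifier number. Among 6418 tested numbered models, 5978 pairs had consecutive numbers, and 157 of these pairs changed in the same direction in BCS against control, where shuffled calls gave a mean of 78.2. The same count was 74 against 33.2 in copper against control and 578 against 418.9 in copper against BCS. In each comparison none of 10000 shuffles reached the observed count (permutation p = 1e-04, the smallest the shuffles can give), which argues against chance placement. Fold changes of consecutive models correlated across models at r = 0.16, 0.21 and 0.20 in the order copper against control, BCS against control, copper against BCS. At a distance of 2 numbers the correlations were 0.04, 0.03 and 0.05. The longest run in copper against BCS held 8 consecutive models that were all higher with copper, from 93-3_5.6A4876 to 93-3_5.6A4883 (singled out after their values were seen), but a run as long was not rare once all 6 longest runs were tested (permutation p = 0.044, adjusted p = 0.13, 1000 shuffles). The other 5 longest runs, in either direction and comparison, held 4 models each. Of these, the run of models that fell in copper against control passed (permutation test, adjusted p = 0.012), and the adjusted p of the other 4 ranged from 0.17 to 0.44. A hypothesis is that the numbers follow the genome, so that neighbouring genes may respond together, which needs coordinates that were not used here. A transcript split over 2 adjacent models stays open as a source of part of the pattern: the median absolute log2 ratio of FPKM within adjacent pairs was 1.61 ± 0.12 (bootstrap SD), over the 578 same-direction pairs of copper against BCS, compared with 1.95 in random pairs with the same mix of directions. Of the adjacent pairs 33.0% lay within 2-fold, compared with 26.3% of the random pairs.

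More models were higher than lower in copper against BCS (67.4% of the called models). The 10 most abundant models held a mean of 7.37% of reads with BCS and 6.4% with copper, and a larger set was not tested. The tables argue against reads taken up by these 10 models as the cause, since leaving them out and rescaling the libraries gave 66.5%. They argue against model length too, since the share was 64.1% in the shortest of 3 equal length classes of numbered models, 73.4% in the middle class and 71.3% in the longest. An overall shift of scale is consistent with the data: the peak of the log2 fold changes of all tested models lay at 0.22 ± 0.021 (bootstrap SD), close to their median of 0.24, and the medians over 5 classes of models by abundance ran from 0.17 to 0.30. The median of all tested models moved by more than this bootstrap SD between libraries, to 0.17 without BCS replicate 1 and 0.38 without BCS replicate 2. The median FPKM of BCS replicate 2 was 15.5, within the copper range of 14.7 to 16.5, while BCS replicates 1 and 3 had 11.1 and 11.8. Among the 100 most abundant models, however, 16 were higher and 24 lower with copper. Median-of-ratios scaling, which centres the libraries on their median, gave 49.8%, while the TPM scale gave 72.3%. FPKM divides out a difference in total RNA content, and no test here separated a shift of scale from a change in the composition of the RNA, so the cause stays open.

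Other splits of the libraries into 3 and 3 gave fewer calls. The real split called 750, 1342 and 2782 models in copper against control, BCS against control and copper against BCS, and the highest of the 9 other splits called 0 in each case. For models changed at least 2-fold the real values were 499, 934 and 1608, and the highest others 0. The real split was thus the 1 split of 10 with a count as large, and 10 splits are too few for a share under 0.05. Each of the 9 other splits also mixes libraries of both groups, so any difference between the groups adds to the spread. A count of 0 in these splits is therefore no measure of what chance gives, and no conclusion is drawn from it.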
